A study of Saccharolobus islandicus with 18 samples.

How the data were processed

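The series measured gene expression by RNA sequencing in cultures of the archaeon Saccharolobus islandicus REY15A. It holds 18 samples in 6 groups of 3, which the labels call biological replicates. The groups were the wild type strain E233S and a strain deleted for sisperR, each mock-treated or treated with hydrogen peroxide (H2O2) for 6 h, and E233S carrying the vector pSeSD, empty or with sisperR for overexpression. Per the labels, 70 μM H2O2 was added at an optical density of 0.2, growth was at 75 °C, and the strains without the vector had uracil in their medium while the vector strains did not. Parts of the labels disagree: the genotype field and the design text name another gene, Sisfha, and the design text names NQO as the treatment. Samples were grouped by their titles and descriptions, which name SisPerR and H2O2 throughout. No time is stated for the vector strains.

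The deposited table gives 1 value per gene and sample in FPKM, as the authors made it (fragments scaled to gene length and library size). The processing notes name CASAVA 2.19, Bowtie2 2.3.4.3, HTSeq 0.9.1 and DESeq2, without their roles, their order, a genome build or the strand setting. In every sample 100% of the values, times gene length, were whole multiples of 1 step within a tolerance of 0.1, so whole reads per gene could be recovered. The library size that the FPKM imply lay between 1.00 and 1.02 times the one that median-of-ratios size factors give. FPKM times length in kilobases summed to between 0.877 and 1.17 times the number the unit scales to, so that size is not the sum of the counted reads. Recovered reads numbered from 3039710 to 3787379 per library. Intervals and shares from these reads cover counting error alone.

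Of 2781 genes, 2628 with a mean of at least 1 FPKM over the 18 samples were tested, and 153 were left out. A gene near 0 in most groups was thus tested only if another group raised that mean. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). It was fitted to all 18 samples with a mean per group, empirical Bayes variances with a trend, 12 residual degrees of freedom and two-sided tests. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The 5 comparisons were deletion against wild type in mock cultures and at H2O2, H2O2 against mock in wild type and in the deletion, and overexpression against the empty vector. A contrast tested whether the H2O2 response differed between the strains. The same fit was tested on simulated data for each comparison, with the read numbers of these libraries and 1 dispersion for all of them (0.0122, the median over genes and groups), so groups whose replicates vary more are not represented. At a true 2-fold change it recovered from 76% of changed genes, for the difference of responses, to 94%, and false calls made up from 3.35% to 7.18% of calls.

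Before the data were examined, 26 gene lists were set by words in the product descriptions, with the genes beside sisperR as one of them, together with the rule for named genes. That rule takes sisperR, the 12 largest changes in each direction among called genes whose groups do not overlap, all members of the peroxide defence and metal ion transport lists, the 5 genes on each side of sisperR, and up to 4 members of each other list with the smallest p. For the difference of responses it takes 6 in each direction. Genes shared between comparisons are the 10 with the largest summed change. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 44 camera calls over the comparisons, 0 hold with an estimated correlation. Words place some genes where their function is not the one the list names: a superoxide dismutase among metal transporters, heterodisulfide reductase subunits under thiol redox, transcription factor B proteins under translation, 3-isopropylmalate dehydratase under central carbon, and the regulator PhoU among toxin-antitoxin genes.

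Product names, domains and coordinates come from the deposited table, which names 1 sequence. A gene table of another strain was not used, and promoters were not searched since no genome sequence was at hand. Reads of near-identical copies such as transposases, and of genes that overlap on opposite strands, may be shared between genes, since the strand setting is not stated. Alternatives were other pseudocounts, filters, scalings, samples in the fit and variance models, a replicate block, and each library left out in turn. Voom on the recovered reads, with the library size of the FPKM or with total reads, was added after the data were seen.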

Results

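Expression was measured in 18 RNA sequencing libraries of Saccharolobus islandicus REY15A, an archaeon that grows in hot acid, in 6 groups of 3 biological replicates. The stated purpose is to learn what SisPerR, a protein of the Fur family of metal-dependent regulators, does to transcription when cells meet H2O2. Wild type mock libraries held from 3187666 to 3787379 counted reads, wild type H2O2 libraries from 3039710 to 3636843, deletion mock from 3234997 to 3457707, deletion H2O2 from 3275670 to 3409823, empty vector from 3294673 to 3515889 and overexpression from 3150732 to 3358667. Values below are FPKM as mean ± SD over 3 replicates, or log2 fold changes ± SE from limma with 3 replicates per group. Genes named for their rank had no overlap between the groups, so each change was seen in 3 of 3 replicates.

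The regulator itself behaved as the strain names state. The gene sisperR (SIRE_RS00280, 49027 to 49437 on the minus strand) stood at 152 ± 14.8 FPKM in wild type mock cultures. In the deletion it stood at 1.24 ± 0.473 FPKM, from 5 reads in 3 libraries against 673 in wild type. That is 0.799% of the wild type level, with an exact (Clopper-Pearson) 95% interval from 0.259% to 1.87%. On overexpression it reached 8520.03 ± 1175 FPKM, 52.0 times the empty vector (interval 48.1 to 56.3). The empty vector replicates stood at 83.6, 206 and 187 FPKM. The intervals in this paragraph pool the reads of the replicates and cover counting error alone, not the spread between cultures. H2O2 raised sisperR in wild type to 330.3 ± 29.6 FPKM, 2.17 times the mock level (interval 1.98 to 2.38). The fitted change of that rise was 1.12 ± 0.38, and its call was lost without wild type mock replicate 1 (1.03), without wild type H2O2 replicate 2 (1.04475) and with a pseudocount of 0.1 (1.12), so the fold stayed about as large. The call was kept under the other alternatives. Limma gave adjusted p = 6.12e-05 from the groups compared alone and 0.000950 with a pseudocount of 5. Voom with the library sizes of the FPKM gave adjusted p = 0.000129.

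The first comparison asks which genes change when SisPerR is missing and no peroxide is added. Among the largest rises were genes annotated with iron, metal or peroxide functions. SIRE_RS02340 (418965 to 419546, plus strand), annotated as a DNA polymerase but carrying a ferritin-like domain of the kind that stores iron, rose from 150.3 ± 38.4 to 47329.7 FPKM, a fitted change of 8.32 ± 0.24. Beside it, the Rieske iron-sulfur protein SIRE_RS02345 (419577 to 419915, plus strand) rose by 7.68 ± 0.35. On the other side, the metal ion transporter SIRE_RS02335 of the Nramp family (417489 to 418655, minus strand) rose by 6.16 ± 0.24, from 1.14 to 152 FPKM. SIRE_RS13310, which joins a rubrerythrin domain to a VIT1/CCC1 transporter domain (2463827 to 2464894, minus strand), rose by 3.87 ± 0.12. Rubrerythrins are iron proteins that reduce peroxide. A second block of adjacent genes rose too: the rubrerythrin SIRE_RS12945 (2398693 to 2399127, minus strand) by 2.66 ± 0.12, from 13977.1 to 87805.5 FPKM, SIRE_RS12940, annotated as a glycerol-3-phosphate dehydrogenase with a cysteine-rich domain, by 2.90 ± 0.19, and SIRE_RS12935 of unknown function by 2.97 ± 0.15.

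**Figure D1:**
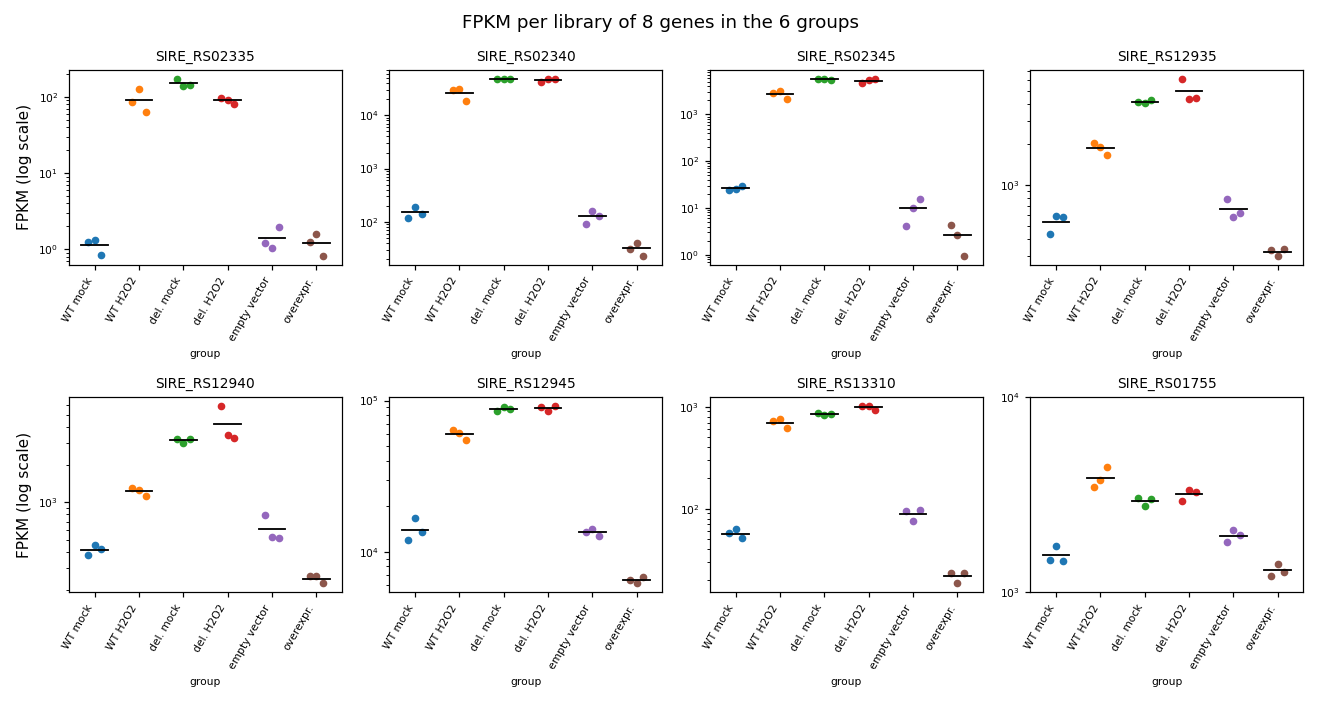
FPKM (log axis) of 8 genes in each of the 18 libraries, by group; points are replicates and black lines are means. All 3 deletion mock libraries lie above all 3 wild type mock libraries for each gene, and SIRE_RS02340 goes from a mean of 150.3 to 47329.7.

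In the list of peroxide and superoxide defence, 4 of 12 members were higher and 2 lower in the deletion (5 and 2 adjusted over the list alone). Camera called the list higher (adjusted p = 0.00675), which was lost at adjusted p = 0.347 with an estimated correlation. Besides SIRE_RS02340, SIRE_RS12945 and SIRE_RS13310, the peroxiredoxin SIRE_RS01755 rose by 0.93 ± 0.10. Of 12 metal ion transport genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0349, and adjusted p = 0.347 with an estimated correlation). They include the ZIP family transporter SIRE_RS11055, at 0.64 ± 0.14. The lower member is a superoxide dismutase, SIRE_RS08545 (-0.43 ± 0.10), whose call was lost without wild type mock replicate 2 (-0.38). Peptide and amino acid transport had 6 of 24 higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.0263, and adjusted p = 0.347 with an estimated correlation). The permease SIRE_RS12515 rose by 0.54 ± 0.09. The nitrate reductase alpha subunit SIRE_RS02290 rose by 1.15 ± 0.14 and the assembly protein SIRE_RS02280 by 1.62 ± 0.21.

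Among the genes lower in the deletion, ribosomal proteins stood out as a list. Of 67, 10 were lower and 0 higher (10 lower adjusted over the list alone; camera adjusted p = 3.42e-06, and adjusted p = 0.347 with an estimated correlation), with L13e (SIRE_RS01170) at -1.26 ± 0.18 and L14e (SIRE_RS08145) at -0.69 ± 0.10. In sulfur and nitrogen assimilation 7 of 33 were lower and 0 higher (9 and 1 adjusted over the list alone), but camera did not call that list (adjusted p = 0.160). Its neighbouring genes SIRE_RS11725, a phosphoadenylyl-sulfate reductase of sulfate assimilation, and the sulfurtransferase SIRE_RS11740 fell (-1.73 ± 0.33 and -1.33 ± 0.25). Flagellin SIRE_RS00615, the filament protein of the swimming organ, fell (-1.10 ± 0.14), as did the CRISPR genes csa5 (SIRE_RS03875, -0.95 ± 0.14) and cas5a (SIRE_RS03885, -0.94 ± 0.15). Large falls were found at the transposase SIRE_RS03810 (-2.68 ± 0.50), SIRE_RS01880 (-2.48 ± 0.21) and a glycerol kinase, SIRE_RS01605 (-2.25 ± 0.29). Of the 10 neighbours of sisperR, 2 were lower, led by the nucleoside hydrolase SIRE_RS00275 (-1.50 ± 0.15), whose coordinates overlap sisperR by 27 bp on the other strand.

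Limma called 393 genes in this comparison, 214 higher and 179 lower, of which 80 changed at least 2-fold (43 higher, 37 lower). The groups did not overlap at 1056 genes (40.2%; chance gives 10%). The count fell to 159 without wild type mock replicate 2, to 210 without deletion mock replicate 1 and to 220 without deletion mock replicate 3. Higher genes were 54.5% of the calls, 38.9% with each library centred on its median and 33.8% with voom on total reads.

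The second comparison asks what H2O2 does in wild type. The same ferritin-like gene SIRE_RS02340 had the largest rise (7.44 ± 0.24, to 26419.9 FPKM), followed by SIRE_RS02345 (6.64 ± 0.35). SIRE_RS02335 rose from 1.14 to 92.0 FPKM and SIRE_RS13310 by 3.59 ± 0.12. Further large rises were in 2 permease genes of an ABC transporter, SIRE_RS11115 (5.49 ± 0.24, from 10.3 to 509 FPKM) and SIRE_RS11110 (5.26 ± 0.20), and in SIRE_RS04585 of unknown function (5.43 ± 0.13, from 114 to 4984 FPKM). Falls were led by SIRE_RS07855 (-3.72 ± 0.17, from 8420 to 655 FPKM), the helix-turn-helix protein SIRE_RS10215 (-3.43 ± 0.16) and SIRE_RS06065 (-3.06 ± 0.15). Reverse gyrase (rgy, SIRE_RS05690), the enzyme that winds DNA in heat-loving organisms, fell (-2.35 ± 0.12), and so did SIRE_RS08775, the nucleotidase that feeds proteins to the proteasome (-2.26 ± 0.12).

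In peroxide and superoxide defence 7 of 12 members were higher and 4 lower with H2O2, the same adjusted over the list alone, and camera did not call the list (adjusted p = 0.268). The rubrerythrin SIRE_RS12945 rose by 2.11 ± 0.12 to 59683.6 FPKM and the peroxiredoxin SIRE_RS01755 by 1.32 ± 0.10, while another peroxiredoxin, SIRE_RS00330, fell (-1.50 ± 0.12). Metal ion transport had 8 of 12 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.0386, and adjusted p = 0.418 with an estimated correlation). Here the ZIP transporter SIRE_RS11055 rose by 3.72 ± 0.14 and the CorA magnesium transporter SIRE_RS03765 by 2.31 ± 0.14. Thiol redox had 8 of 13 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.0201, and adjusted p = 0.418 with an estimated correlation). Its largest rises were heterodisulfide reductase subunits, named after an enzyme of methanogens, with SIRE_RS04940 at 2.82 ± 0.10. Iron-sulfur cluster assembly proteins sufB (SIRE_RS05870) and SIRE_RS05865 rose by 1.96 ± 0.08 and 1.65 ± 0.09. In that list 8 of 17 were higher and 4 lower, the same adjusted over the list alone, with no camera call (adjusted p = 0.179).

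In 2 lists of toxin and mobile genes, more members were higher than lower in wild type at H2O2. Toxin-antitoxin genes had 46 of 72 higher and 8 lower (47 and 8 adjusted over the list alone; camera adjusted p = 0.000533, and adjusted p = 0.418 with an estimated correlation), with the VapC toxin SIRE_RS01895 at 4.20 ± 0.20 and the phosphate regulator PhoU (SIRE_RS07060) at 2.10 ± 0.10. Of 72 transposases and integrases tested 39 were higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.000938, and adjusted p = 0.418 with an estimated correlation). The IS1 transposase SIRE_RS00655 rose by 4.87 ± 0.44. Genes of low level were more often higher than lower. Of 295 genes with a mean of up to 10 FPKM in the deletion mock and empty vector libraries, 150 were higher and 3 lower, with a median of 1.15, whereas in the 250 genes of the highest levels the median was -0.37. The filter takes in the wild type H2O2 libraries, so genes near 0 elsewhere may have been tested only for being high there. Genes near 0 also can hardly be called lower. Part of this imbalance may follow from both limits, also for the transposases and integrases, of which 72 of 169 were tested. Over the 174 genes under 10 FPKM and of at least 300 nt the median was 1.36, and 0.45 after quantile normalization.

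In 5 further lists that camera called, more members were lower than higher in the same cultures. Of 51 genes of pyrimidine and purine biosynthesis 33 were lower and 4 higher, the same adjusted over the list alone (camera adjusted p = 0.000507, and adjusted p = 0.544 with an estimated correlation), among them the purine gene SIRE_RS07020 (-1.79 ± 0.10). Ribosomal proteins had 28 of 67 lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 0.000533, and adjusted p = 0.544 with an estimated correlation). S17 (SIRE_RS06585) stood at -1.37 ± 0.14, and L13e (SIRE_RS01170) went the other way at 1.61 ± 0.18. Amino acid biosynthesis had 40 of 80 lower and 14 higher (40 and 15 adjusted over the list alone; camera adjusted p = 0.00886, and adjusted p = 0.660 with an estimated correlation). Peptide and amino acid transport had 15 of 24 lower and 4 higher, the same adjusted over the list alone (camera adjusted p = 0.0450, and adjusted p = 0.544 with an estimated correlation). Translation and tRNA charging had 20 of 44 lower and 6 higher, the same adjusted over the list alone (camera adjusted p = 0.0450, and adjusted p = 0.660 with an estimated correlation). In the glyoxylate bypass and the making of sugars, isocitrate lyase aceA (SIRE_RS03750) rose by 2.26 ± 0.12 and ppsA (SIRE_RS06060) by 1.84 ± 0.12.

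**Figure D2:**
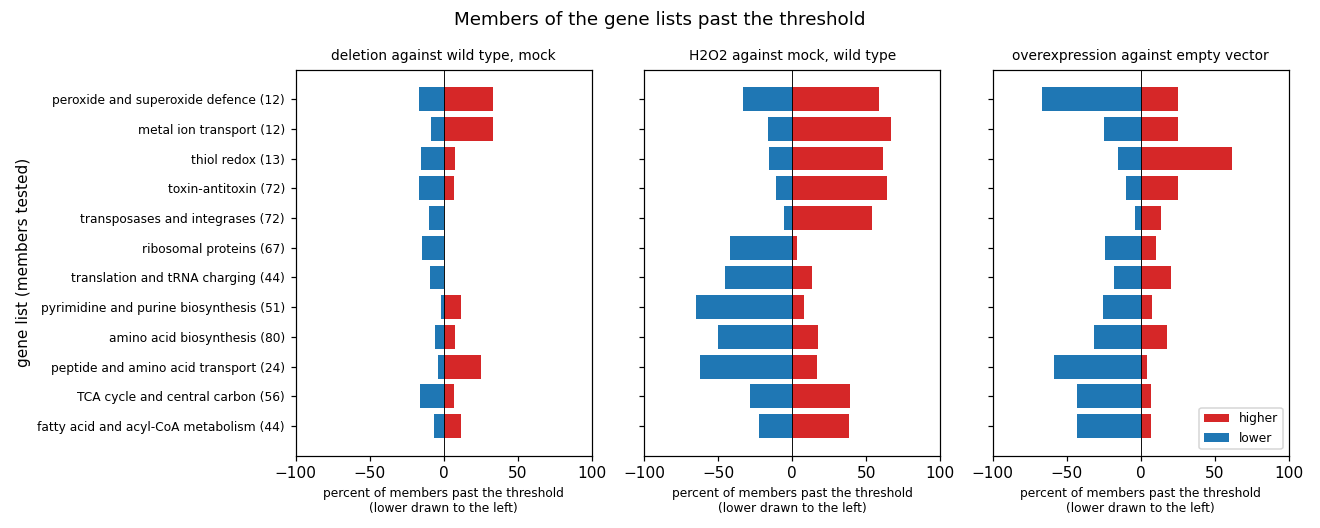
Percent of the tested members of 12 gene lists past the threshold in 3 comparisons, with higher members drawn to the right and lower ones to the left. With H2O2 in wild type 46 of 72 toxin-antitoxin genes were higher, while 33 of 51 genes of pyrimidine and purine biosynthesis were lower. The directions of the central carbon list in wild type, and of amino acid biosynthesis and fatty acid metabolism in the deletion, flip with each library centred on its median.

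Limma called 1593 genes with H2O2 in wild type, 841 higher and 752 lower, of which 447 rose and 170 fell at least 2-fold. The groups did not overlap at 1810 genes (68.9%; chance gives 10%). Higher genes were 52.8% of calls, 41.2% after quantile normalization and 61.0% with voom on total reads. The median of all genes shifted by -0.11 with centring, -0.18 with quantile normalization and 0.10 with voom on total reads.

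The third comparison asks what H2O2 does when SisPerR is missing. Several of the genes that moved most in wild type stayed near their level in the deletion mock cultures. SIRE_RS02340 stood at 47329.7 FPKM in mock and 46174.5 in H2O2 cultures of the deletion, the rubrerythrin SIRE_RS12945 at 87805.5 and 89299.5, and SIRE_RS13310 at 848 and 986. SIRE_RS11115, which H2O2 raised in wild type to 509 FPKM, stood at 12.3 in mock and 10.5 in H2O2 cultures of the deletion, and the ZIP transporter SIRE_RS11055 at 192 and 176. SIRE_RS07855, which fell in wild type to 655 FPKM, stood at 7408 and 7511. Over the 447 genes that rose at least 2-fold in wild type the median change was 1.81 there and 0.01 in the deletion (quartiles -0.26 to 0.22).

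Limma called 0 genes with H2O2 in the deletion, with 372 at an unadjusted p under 0.05. Voom on the recovered reads called 43 genes with the library sizes of the FPKM, all of them lower, and 52 with total reads. Among the 43 was the Nramp transporter SIRE_RS02335, which stood at 152 FPKM in mock and 89.9 in H2O2 cultures. The fit of the groups compared alone called 23 genes and the fit without a variance trend called 1. Without deletion H2O2 replicate 1, a library that stood apart from its group, limma called 6 genes, and without deletion mock replicate 3 it called 1. The groups did not overlap at 609 genes (23.2%; chance gives 10%). Camera called 9 lists with small medians, such as 0.17 over the 56 genes of the central carbon list (adjusted p = 1.53e-08, and adjusted p = 0.500 with an estimated correlation), where 0 members passed the threshold, over all genes or adjusted over the list alone. The other 8 calls were lost with an estimated correlation as well, and fry called 0 lists.

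**Figure D3:**
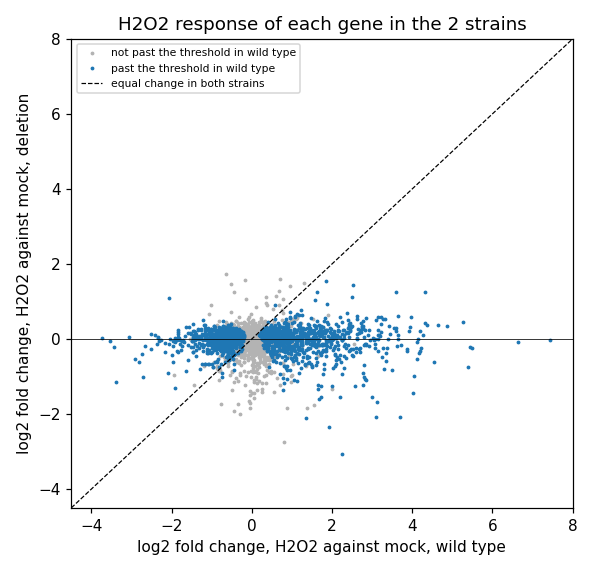
Log2 fold change of each gene with H2O2 in the deletion (vertical axis) against that in wild type (horizontal axis); blue points passed the threshold in wild type and the dashed line marks equal change. Blue points spread along the horizontal axis up to 7.44 for SIRE_RS02340 and most lie nearer 0 on the vertical axis, with exceptions such as SIRE_RS05770 (1.91 and -2.36).

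The difference between the responses was tested directly. It was largest at SIRE_RS02340 (-7.48), SIRE_RS02345 (-6.72) and SIRE_RS02335 (-6.14), whose levels in the deletion were high before H2O2 was added, followed by SIRE_RS14790 (-5.77), SIRE_RS11115 (-5.73) and SIRE_RS04585 (-5.64), which H2O2 did not raise in the deletion. In the other direction the difference was 3.74 at SIRE_RS07855, 3.22 at SIRE_RS10215 and 2.52 at hmgA (SIRE_RS07415), which makes mevalonate for membrane lipids. Toxin-antitoxin genes were lower in this difference at 40 of 72 members and higher at 7, and pyrimidine and purine genes higher at 31 of 51 and lower at 3. Camera gave adjusted p = 0.000221 and 0.000103 for these lists, and adjusted p = 0.384 and 0.565 with an estimated correlation. Limma called 1313 genes, 629 higher and 684 lower. Higher genes were 47.9% of calls, 60.1% after quantile normalization and 34.5% with voom on total reads, and the median of all genes shifted by 0.16 with centring, 0.22 with quantile normalization and -0.19 with voom on total reads.

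The fourth comparison sets the deletion against wild type with H2O2 in both. Among the genes lower in the deletion were some of those that H2O2 raised most in wild type, with SIRE_RS04585 at -6.07 ± 0.13, SIRE_RS11115 at -5.52 ± 0.24, the IS1 transposase SIRE_RS00655 at -5.50 ± 0.44 and the ZIP transporter SIRE_RS11055 at -3.23 ± 0.14. Higher in the deletion were SIRE_RS07855 (3.57 ± 0.17), SIRE_RS06065 (2.87 ± 0.15) and the amino acid permease SIRE_RS12515 (2.31 ± 0.09). Of the genes that led the rises without peroxide, SIRE_RS12940, SIRE_RS12935 and SIRE_RS02345 were still higher in the deletion here (1.73 ± 0.19, 1.39 ± 0.15 and 0.96 ± 0.35). SIRE_RS02335 differed by 0.02 ± 0.24 and was not called, while SIRE_RS13310 was higher by 0.50 ± 0.12. SIRE_RS02340 and SIRE_RS12945 were higher by 0.84 ± 0.24 and 0.58 ± 0.12, calls lost under quantile normalization, where both differed by 0. That scaling gives genes of the same rank the same value, so it cannot show a difference for genes that keep their rank.

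By list, 36 of 51 pyrimidine and purine genes were higher in the deletion at H2O2 and 4 lower, the same adjusted over the list alone (camera adjusted p = 2.29e-05, and adjusted p = 0.502 with an estimated correlation). Amino acid biosynthesis had 49 of 80 higher and 14 lower, the same adjusted over the list alone (camera adjusted p = 0.000172, and adjusted p = 0.673 with an estimated correlation). Toxin-antitoxin genes had 49 of 72 lower and 8 higher, the same adjusted over the list alone (camera adjusted p = 6.33e-05, and adjusted p = 0.276 with an estimated correlation). Transposases and integrases had 40 of 72 lower and 4 higher, the same adjusted over the list alone (camera adjusted p = 0.000313, and adjusted p = 0.336 with an estimated correlation). Thiol redox had 9 of 13 lower and 3 higher, the same adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.336 with an estimated correlation). In peroxide and superoxide defence 6 of 12 were higher and 3 lower, the same adjusted over the list alone, with no camera call (adjusted p = 0.467). With voom on total reads that list turned to 4 higher and 5 lower. Limma called 1661 genes, 792 higher and 869 lower, of which 186 were higher and 503 lower at least 2-fold, and the groups did not overlap at 1742 genes (66.3%; chance gives 10%). Higher genes were 47.7% of calls, 59.5% after quantile normalization and 30.9% with voom on total reads, and the median of all genes shifted by 0.10, 0.19 and -0.27 with centring, quantile normalization and voom on total reads.

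The fifth comparison asks what more SisPerR does, against the empty vector. After sisperR itself (5.83 ± 0.38), the largest rises were the winged helix-turn-helix regulator SIRE_RS13575 (4.33 ± 0.26, from 185 to 3532 FPKM), the CRISPR-associated gene SIRE_RS07845 (3.79 ± 0.25), SIRE_RS05770 of unknown function (3.71 ± 0.55) and the ABC transporter genes SIRE_RS03000 (3.16 ± 0.17) and SIRE_RS03005 (2.57 ± 0.13). The largest falls were both subunits of 3-isopropylmalate dehydratase of leucine synthesis, SIRE_RS01310 (-3.57 ± 0.10, from 746 to 62.5 FPKM) and SIRE_RS01305 (-3.35 ± 0.09). SIRE_RS10125 (-3.56 ± 0.11) and the transporters SIRE_RS10780 (-3.10 ± 0.14), SIRE_RS03545 (-2.95 ± 0.12) and SIRE_RS12550 (-2.80 ± 0.13) fell as well. These 4 genes stood at 6021, 969, 691 and 365 FPKM in the empty vector strain and at 242, 29.0, 105 and 79.6 in wild type mock cultures without the vector. The falls are thus from levels found with the vector and its medium, to 509, 112, 88.7 and 51.5 FPKM. A run of genes with a cytosine permease, SIRE_RS02840 (-2.80 ± 0.13), and the hydantoinases SIRE_RS02830 (-2.72 ± 0.22) and SIRE_RS02855 (-2.67 ± 0.18), enzymes that open ring compounds, fell with them.

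In peroxide and superoxide defence 8 of 12 members were lower on overexpression and 3 higher (8 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.118). The rubrerythrin SIRE_RS12945 fell (-1.06 ± 0.12), as did SIRE_RS02340 (-1.98 ± 0.24), SIRE_RS13310 (-1.98 ± 0.12) and the peroxiredoxin SIRE_RS03670 (-1.51 ± 0.19). SIRE_RS03670 stood at 183 FPKM in wild type mock cultures, 781 in the empty vector and 269 on overexpression, and 5 of the 12 members were higher in the empty vector strain than in wild type. Superoxide dismutase SIRE_RS08545 rose by 0.74 ± 0.10. Metal ion transport had 3 of 12 higher and 3 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.791). The transporter SIRE_RS02335 stood at 1.41 ± 0.491 FPKM in the empty vector and 1.21 ± 0.377 on overexpression and was not called.

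In the 3 lists that camera called, more members were lower than higher. Many members of these lists were higher in the empty vector strain than in wild type: 11 of 24 for peptide and amino acid transport, 37 of 56 for central carbon and 23 of 44 for fatty acids. Peptide and amino acid transport had 14 of 24 lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.0146, and adjusted p = 0.756 with an estimated correlation), with SIRE_RS12515 at -1.56 ± 0.09. The central carbon list had 24 of 56 lower and 4 higher (24 and 5 adjusted over the list alone; camera adjusted p = 0.0146, and adjusted p = 0.756 with an estimated correlation). Its members with the largest falls were the isopropylmalate dehydratase subunits above, of leucine synthesis, followed by malate synthase SIRE_RS03745 of the glyoxylate bypass (-1.42 ± 0.07). Fatty acid and acyl-CoA metabolism had 19 of 44 lower and 3 higher, the same adjusted over the list alone (camera adjusted p = 0.0408, and adjusted p = 0.756 with an estimated correlation), with the ligase SIRE_RS12395 at -1.27 ± 0.14. Sugar transport and glycoside hydrolysis had 12 of 29 lower and 3 higher (13 and 4 adjusted over the list alone) with no camera call (adjusted p = 0.118). Flagellin SIRE_RS00615 rose by 1.63 ± 0.14 and a transcription factor B protein, SIRE_RS08730, by 2.13 ± 0.15. The flagellin stood at 108 FPKM in wild type mock cultures, 19.5 in the empty vector and 62.2 on overexpression, so it stayed below wild type. Of the 10 neighbours of sisperR, 0 were called by limma.

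Limma called 1248 genes, 624 higher and 624 lower, of which 219 rose and 156 fell at least 2-fold, and the groups did not overlap at 1496 genes (56.9%; chance gives 10%). Without empty vector replicate 1, a library that stood apart from its group, 1116 genes were called. Higher genes were 50% of calls and 60.2% with voom on total reads, which shifted the median of all genes by 0.10.

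Genes shared between comparisons were counted to ask whether loss, excess and peroxide act on the same genes. Higher in the deletion and lower on overexpression were 67 genes, where independent lists would give 50.8 (one-sided Fisher's exact test across genes, p = 0.00512), led by SIRE_RS02340, SIRE_RS02345, SIRE_RS13310, SIRE_RS12940, SIRE_RS12935 and SIRE_RS12945. Lower in the deletion and higher on overexpression were 58 genes, against 42.5 (Fisher's exact test, p = 0.00397), with L13e (SIRE_RS01170) and SIRE_RS03005 after sisperR. Higher with H2O2 in wild type and higher in the deletion without it were 66 genes, against 68.5 (Fisher's exact test, p = 0.674). These comparisons share the wild type mock libraries, so part of the overlap may come from them. Unchanged groups simulated against them gave at most 0 shared genes, a value that leaves out the effects of both. Over all genes the covariance of the changes was 0.0487 where the simulated groups gave 0.0357, and the correlation 0.08 where they gave 0.49. The 66 are led by SIRE_RS02340, SIRE_RS02345, SIRE_RS02335 and SIRE_RS13310. Lower in both of these comparisons were also 66 genes, against 51.2 (Fisher's exact test, p = 0.00816). In opposite directions, 74 were lower with H2O2 and higher in the deletion, against 61.2 (Fisher's exact test, p = 0.0279), and 63 were higher with H2O2 and lower in the deletion, against 57.3 (Fisher's exact test, p = 0.193). Peroxide and excess did not act in opposite directions on more genes than independent lists would share. Higher with H2O2 and lower on overexpression were 135 genes, against 199.7, and lower with H2O2 and higher on overexpression were 110, against 178.6 (Fisher's exact test, p = 1 for both), while the changes correlated at 0.21 over all genes.

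Genes are not independent replicates, and these are 8 of 16 overlaps computed. The first 3 counts, of 67, 58 and 66 genes, fell without wild type mock replicate 2, to 36, 22 and 31, without deletion mock replicate 1, to 36, 35 and 35, and without deletion mock replicate 3, to 42, 30 and 43. The first of them fell to 37 with voom on total reads and the last to 43 with centring.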

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

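The tests of precision in the other genes, of unexposed cultures, of read numbers, of scaling and of the gene beside sisperR were chosen only after the results were seen. A difference between strains brought up the results listed in this paragraph. The H2O2 response differed between deletion and wild type at 1313 genes. The response was lower in the deletion at SIRE_RS02340 (-7.48), SIRE_RS02345 (-6.72), SIRE_RS02335 (-6.14), SIRE_RS14790 (-5.77), SIRE_RS11115 (-5.73) and SIRE_RS04585 (-5.64). It was higher at SIRE_RS07855 (3.74), SIRE_RS10215 (3.22), SIRE_RS05605 (3.15), SIRE_RS06065 (3.12), SIRE_RS07425 (2.66) and SIRE_RS07415 (2.52).

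That 0 genes passed the threshold with H2O2 in the deletion was weighed first. Too little precision to see an equal response was excluded only for genes that changed at least 2-fold in wild type. For 96.8% of them the 95% interval in the deletion left out the wild type change. A weaker response of these genes, missed for lack of precision, was not excluded. For the 2011 other genes too little precision remained open: 41 changed at least 2-fold at an unadjusted p under 0.05, 36 of them lower, and the highest of the other splits gave 14. Cultures that were not exposed to H2O2 remained open: the real split of the 6 deletion libraries gave 372 genes at an unadjusted p under 0.05, and the highest of the other splits gave 207, which are too few splits for a share under 0.05. A deletion strain that no longer responds, or that removes the peroxide before 6 h, may give the same values, and these data do not part them.

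Genes of low level that were higher with H2O2 in wild type were weighed next, on the 174 genes under 10 FPKM that are at least 300 nt long, of which 115 were higher and 1 lower. Genes near 0 can hardly be called lower, and some may have passed the filter only through the wild type H2O2 libraries. DNA in those libraries would add a similar FPKM to every gene. The 10th percentile of the added FPKM was -0.492% of the median (upper bound 11.8%), which argues against that. It does not exclude DNA, since 19 of the 174 genes gained no FPKM and the set holds 29 transposases, whose reads may be shared between copies. Which of the 19 are transposases was not tested. The read ratio of H2O2 to mock was 0.987, which excludes more reads. Centring kept 91.7% of the median change. It moves all genes of a library by the same value, and it shifted the median of all genes by -0.11 here, so what it kept followed from that shift. Centring cannot test a scaling that acts more on genes of low level. Quantile normalization, which makes the distributions equal by construction, kept 33.1%, so such a scaling remained open.

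The gene beside sisperR, SIRE_RS00275, was lower in the deletion. A local effect of the deleted stretch predicts that overexpression from the plasmid does not raise it by as much as it fell. The upper 95% bound of its change there was 0.36, so this was met. It does not favour a local effect, since of 179 genes lower in the deletion only 58 were higher on overexpression. A local effect remained open. Reads of the sisperR transcript counted for SIRE_RS00275 were excluded only as the source of the whole fall. Its upper bound with H2O2 in wild type was 0.52, under the 0.82 predicted from the rise of sisperR. That prediction takes its own transcript as unchanged by H2O2. A part of the fall from such reads remained open.

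Splits of 3 against 3 libraries are too few for a share under 0.05. The real split and the highest other gave 393 and 0 genes (deletion mock), 1593 and 0 (H2O2 in wild type), 0 and 1 (H2O2 in the deletion), 1661 and 1 (deletion at H2O2) and 1248 and 0 (overexpression), so that 1, 1, 10, 1 and 1 of 10 splits reached the real count. For the difference of responses 2 of 100 splits reached it, the highest at 1337 from a split that kept the H2O2 libraries apart by strain. For the overlaps 1, 1 and 2 of 100 did, with 0, 0 and 630 as the highest others, the last from a split that called the wild type H2O2 libraries mock. Other splits of the deletion mock and overexpression libraries called 0 genes, so draws that mixed them had none to share. These shares thus do not test whether the lists overlap more than independent lists would. The third count, 66, lay below the 68.5 of independent lists.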

How the results depend on the processing

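The voom fits were chosen only after the data were seen. Of 13787 values of named genes under the alternatives, 13446 kept direction and side of the threshold, 262 lost it, 77 gained it and 2 reversed. The reversals were SIRE_RS12025 (-0.0298) and SIRE_RS03185 (-0.26), both in the deletion against wild type at H2O2 with voom on total reads, a scaling that shifted the median of all genes by -0.27 there and moved these from 0.24 and 0.01. With H2O2 in the deletion, where the fit called 0 genes, the groups compared alone gave 23, no variance trend 1, and voom 43 with the library sizes of the FPKM and 52 with total reads; the cause was not tested. A limit of at least 2-fold, which keeps fewer genes by construction, left 80 genes in the deletion mock comparison, 617 with H2O2 in wild type, 689 in the deletion at H2O2, 375 on overexpression and 651 for the difference of responses. It left 6 genes higher in the deletion and lower on overexpression, 11 the other way round, and 14 higher in the deletion and with H2O2. The first of these overlaps had 37 genes with voom on total reads and the last had 43 with centring; the cause was not tested. Of 44 camera calls 0 were kept with an estimated correlation, while fry gave 87. With each library left out, which leaves fewer samples, the calls ranged from 159 to 327 (deletion mock), 1408 to 1550 (H2O2 in wild type), 0 to 6 (H2O2 in the deletion), 1507 to 1632 (deletion at H2O2), 1057 to 1183 (overexpression) and 1157 to 1301 (difference of responses). The 3 overlaps ranged from 36 to 78, 22 to 69 and 31 to 71. The replicate numbers did not pair the samples, with correlations of same-numbered libraries between -0.15 and 0.11, and a replicate block gave 406, 1605, 0, 1690, 1279 and 1321 calls and overlaps of 67, 69 and 66. The planned count tools (edgeR and DESeq2, with TMM or size factors) were not run, and voom on the recovered reads was run in their place. Depth limits genes of few reads: 153 of 2781 were below the filter, and at 1.5-fold the simulated recovery for the difference of responses was 12%.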

Other observations

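The tests of this part were chosen only after the results were seen. The empty vector strain and wild type without the vector, both without H2O2, differ at least by the plasmid and by uracil in the medium. No time is stated for the vector strains, and other differences between these cultures were not tested. These strains thus form no comparison of SisPerR. Between them 1067 genes passed the threshold, 555 higher and 512 lower with the vector. Orotate phosphoribosyltransferase SIRE_RS07075, which makes uridine nucleotides, was higher (4.08, from 15.1 to 273 FPKM), as were genes of an ABC sugar transporter, with SIRE_RS11085 at 5.22 and SIRE_RS11075 at 5.24, and the transporter SIRE_RS10780 (5.02, from 29.0 to 969 FPKM). Flagellin SIRE_RS00615 was lower (-2.41). In the central carbon list 37 of 56 were higher and 2 lower, and of 67 ribosomal proteins 19 were lower and 0 higher.

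If SisPerR holds genes down, those that rise in its absence should fall when it is in excess. Of 43 genes at least 2-fold higher in the deletion, 11 were lower on overexpression, or 25.6%, against 23.7% of all tested genes (one-sided Fisher's exact test across genes, p = 0.446). Genes near the floor in the empty vector can hardly fall further, such as SIRE_RS02335 at 1.41 FPKM there and 1.21 on overexpression. The share counts such genes as not falling. The hypothesis remained open for the genes as a class. A set of 6 genes was picked for passing 3 limits at once, so it is no test of that hypothesis: SIRE_RS02340, SIRE_RS02345, SIRE_RS12935, SIRE_RS12940, SIRE_RS12945 and SIRE_RS13310 were at least 2-fold higher in the deletion, higher with H2O2 in wild type and lower on overexpression. Of these, 5 lay within 2 genes of another of the set, which 0 of 10000 random sets of the same size did. Genes picked for a shared pattern were not compared with other such sets, so this is a description of where they lie.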
